A study of Oryza sativa Japonica Group with 39 samples.

How the data were processed

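The series measured rice (Oryza sativa cv. Nipponbare) transcript levels on 39 Agilent spotted-oligonucleotide arrays of 22575 features. Each array was a self-hybridisation: the same RNA was labelled with Cy3 and with Cy5, so the 2 channels repeat 1 measurement and their ratio holds no biological contrast. Array design 1 (31 arrays, 21938 rice probes) and array design 2 (8 arrays, 21495 rice probes) share 20710 complementary DNA accessions, of which 5378 have an unknown description. Genes are named by these accessions and by the product in the platform's best-hit description, which is often that of another species. A table pairing locus tags with symbols matched 0 of the accessions and 0 of the 24 key genes listed by locus, so no chromosome position is given and the genes chosen by locus could not be looked up.

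The deposited scanner files hold, per the file headers, the mean spot intensity and the median local background intensity of each channel, on a linear scale and before any normalization. They also hold Feature Extraction's processed signals. The authors' value tables hold the log10 ratio of Cy5 to Cy3 after the dye normalization of Agilent Feature Extraction, version 8.1.1.1 per the labels. These log10 ratios were set against the scanner files' log ratio column and matched it within 5e-10 on design 1, except shoot array 2 (0.00443), and within 5e-08 on design 2. Medians of the value-table columns ran from -0.00983 to 0.00122 on the log10 scale. The scale (log10), the direction (Cy5 over Cy3) and the centring near 0 were therefore settled from the values. Because these tables hold only ratios of an RNA to itself, expression levels were computed from the deposited intensity columns.

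Intensities were background-corrected by normexp with an offset of 50, normalised within each array by loess with control features at weight 0, and between arrays of each design by Aquantile, in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table). The level of a probe on an array was the mean of its Cy3 and Cy5 log2 signals. Spots that Feature Extraction marked as saturated were kept, and uneven or outlying spots were set aside. A probe was well above background where both channels passed Feature Extraction's test against background. The share of probes well above background ran from 49.9% to 98.6% between arrays.

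Groups were taken from the labels. The labels call the 7 shoot arrays of design 1 technical replicates, so they were averaged to 1 sample (separate plants would call for the fit with separate shoot arrays), and the 3 shoot arrays of design 2 made from total RNA were averaged likewise. In the treatment fit, 13 samples were used (untreated shoot, and 3 time points each of cold, polyethylene glycol, flooding with lay-down, and flooding), with 8 residual degrees of freedom. Time points stood in for replicates, and the lone shoot sample was assumed to vary like the treated ones. Contrasts were each treatment against untreated shoot, each treatment against the mean of the other 3 treatments, and flooding with lay-down against flooding. A separate fit set 4 callus stages against 7 plant organs (9 residual degrees of freedom). A further fit set germinated seed against shoot within each design (1 residual degree of freedom). Dye bias was tested as the mean log2 ratio of Cy5 to Cy3 against 0. All were limma fits (lmFit, then eBayes with an intensity trend, 2-sided), on probes well above background in at least 3 samples (2 for germinated seed), called at a Benjamini-Hochberg adjusted p of 0.05. P-values measure only the spread between these samples, and not variation between independently grown plants. In the treatment fit the samples are a technical set and time points. In the callus fit the spread is that between callus stages and between different organs.

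Conditions with 1 array have no test. Their probes were counted at a 2-fold difference from the mean of the technical shoot arrays of the same design and RNA preparation, with the higher side well above background. Beside each stands the same count against the shoot array scanned on the same day. Scan days were read from the scanner file headers and used as batches. For cold and polyethylene glycol, scan day was fitted as a block, and for callus likewise. No shoot array was scanned on the days of the flood treatments, so the nearest day's shoot array was used there as a stand-in.

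The 35 gene lists, the comparisons, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. Lists were built from words in the descriptions and tested by camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of each comparison. For single arrays, each list median was ranked among 10000 random lists matched on level. Genes were named by rule: up to 10 of the largest called increases and decreases in which all samples of the group lay on 1 side of the reference, with a named product and 1 probe per gene, 6 on each side for single arrays, and up to 4 members of each list described. The text gives a selection of these.

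The procedure was tested on simulated data built from these arrays. For cold against shoot it recovered 78.8%, 26.9% and 0% of probes changed 4-fold, 2-fold and 1.5-fold among 21290 probes. For cold against the other treatments the shares were 95.5%, 80.6% and 49.3%, while 21 unchanged probes were also called, against 0 to 9 in each other comparison. For flooding with lay-down against shoot they were 80.3%, 25.4% and 0%, against the other treatments 97.0%, 80.6% and 23.9%, and against flooding 90.9%, 50.7% and 11.9%, each among 21290 probes. For callus they were 77.3%, 25.4% and 11.9% among 20160 probes, and for germinated seed 100%, 92.5% and 20.9% among 20380. The dye test recovered 100% at each fold among 20049 probes, and a single array recovered 99.0% of 4-fold changes among 21938. For germinated seed and the single array the simulated spread was a chosen value, equal for every probe, so those shares follow from that choice. The technical spread of the shoot arrays was also chosen, and no scan-day effect was simulated. The shares are therefore not the power in the real data. A simulated shifted list gave a camera p of 2.47e-34 with the preset correlation and 6.94e-07 with the estimated one, and an unchanged list gave 0.426 and 0.392.

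Alternatives covered Feature Extraction's processed signals, a shift to a common 75th percentile in place of Aquantile, each channel alone, no filter on dim probes, separate shoot arrays, scan day as a random block (consensus correlation 0.498), hours of treatment as a block, leaving out each array, and other choices of shoot array. The submitters' value tables could not replace the levels, since they hold ratios only. No array was left out of the data description.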

Results

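Transcript levels were measured in 39 arrays of rice shoots, other organs, cultured callus and stress-treated seedlings. Seedlings were 10 days old, at the 3-leaf stage, and grown hydroponically. Design 1 held 7 arrays of untreated shoot, labelled as technical replicates, and 1 array each of root, panicle before heading, shoot apex, flag leaf at booting and whole germinated seed at 4 days. It also held callus at 7, 21, 35 and 42 days of incubation (primary, propagated, white and green) and plants regenerated by 52 days. Treated shoots came from cold at 10 °C (24, 48 and 72 h), 25% polyethylene glycol, or PEG, an osmoticum (1, 9 and 24 h), and flooding with the plants laid down (6, 24 and 48 h). Others came from flooding alone (24, 48 and 72 h), 260 mM mannitol (24 h) and 150 mM NaCl (24 h). Design 2 held 4 technical shoot arrays, germinated seed, plants laid down for 24 h, and both flood treatments at 1 h.

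Median Cy3 intensity ran from 130 (shoot 7) to 581 (germinated seed on design 2), and median Cy5 intensity from 82.1 (green callus) to 1196. On 1 scan day, the 4 arrays of shoot 7, white callus, green callus and regenerated plant had between 49.9% and 58.1% of probes well above background. PEG 9 h had 66.9%, with a median Cy5 intensity of 106 against 331 for Cy3, and every other array had 81.3% or more. Shoots 1 and 4 to 7 correlated at 0.946 to 0.990 across probes. Shoot 2 correlated with those 5 at only 0.770 to 0.869, and at 0.975 to 0.977 with the mannitol and salt arrays of its own scan day. Shoot 3 correlated with them at 0.914 to 0.957. In 3288 probes shoot 2 lay 2-fold or more from the mean of the other 6 shoot arrays, against 62 to 417 probes for each of the others. For design 2, shoots 9 to 11 correlated at 0.977 to 0.988, and shoot 8, made from messenger RNA, at 0.924 to 0.947 with them.

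**Figure D1:**
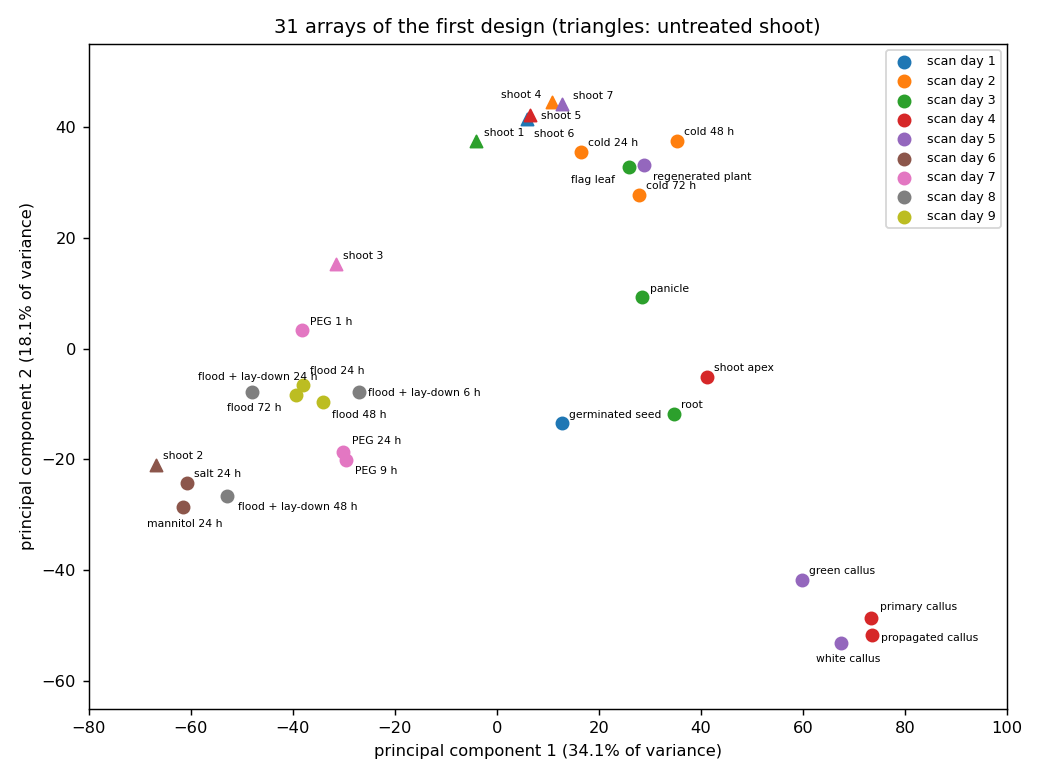
The 31 arrays of design 1 are plotted on principal component 1 (34.1% of variance) and component 2 (18.1%), coloured by scan day, with triangles for untreated shoot. Shoot 2 lies beside mannitol and salt, shoot 3 lies beside the PEG 1 h array, and the callus arrays stand apart from the plant organs.

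Scaling moved the median of all probes by over 0.1 in several comparisons. With processed signals it stood at -0.24 for cold against shoot, -0.30 for cold against the other treatments, 0.23 and 0.16 for PEG, 0.14 and 0.11 for flooding with lay-down, 0.12 for flooding against shoot, 0.13 for germinated seed, -0.17 for flag leaf, -0.10 for regenerated plant and 0.11 for lay-down. With a common 75th percentile it stood at -0.21 for cold against shoot, 0.21 for PEG against the other treatments, -0.17 for flooding with lay-down against shoot, -0.20 and -0.12 for flooding, 0.26 for callus, -0.24 for flag leaf, 0.19 for regenerated plant, -0.17 for mannitol and -0.18 for salt. The changes below are relative to the median of all probes.

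What cold changed in the shoot was asked by setting the 3 cold time points against untreated shoot. The largest increases included an abscisic acid-responsive protein (AK063578), at log2 4.55 ± 0.36 (SE, n = 3 time points here and below), and genes matching protein phosphatases 2C, a family with members that restrain abscisic acid signalling (AK063334, 4.47 ± 0.51, and AK069274, 3.73 ± 0.43). A stress-induced lipocalin, one of a family of small ligand-binding proteins (AK071108), rose by 3.99 ± 0.79. Oshox6, a homeodomain leucine zipper transcription factor (AK063685), rose by 3.99 ± 0.74 on the 2 cold arrays that measured it. The subunit of the Clp protease (AK068727), which unfolds proteins for degradation, rose by 3.72 ± 0.55.

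Among heat shock proteins, which are chaperones, 8 of 69 rose and 2 fell, 12 adjusted over the list alone, and the list as a whole did not pass (median 0.20, adjusted p = 0.225). Increases were found in a SB100 match (AK064436, 3.86 ± 0.42), an 18 kDa protein (AK071240, 3.37 ± 0.62) and a 70 kDa protein (AK109474, 3.19 ± 0.66). Proteasome subunits, which degrade tagged proteins, were higher as a list (median 0.50, adjusted p = 0.000144, and adjusted p = 0.782 with an estimated correlation). Of these, 6 of 52 rose and 0 fell, 8 adjusted over the list alone. These included regulatory subunit S2 (AK105609, 1.36 ± 0.34), OsRPN11 (AK109403, 1.34 ± 0.32, n = 2) and subunit C2 (AK059589, 1.26 ± 0.32). Enzymes that remove reactive oxygen included monodehydroascorbate reductase, which recycles ascorbate (AK102459, 3.32 ± 0.32), and glutathione peroxidase 1 (AK062772, 2.27 ± 0.48). In all, 4 of 32 members of that list rose while 0 fell, 4 adjusted over the list alone, but the list did not pass (median -0.19, mean 0.00, adjusted p = 0.656).

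Photosynthesis genes were lower in cold, but with an estimated correlation every list in this paragraph lost its call (adjusted p = 0.782). The list of light harvesting and photosystems had a median of -0.88 (36 probes, adjusted p = 0.0074), though 1 member alone fell over all probes, 1 adjusted over the list alone: a photosystem II 10 kDa protein (AK062172, -4.32 ± 0.69). A small subunit of Rubisco, the enzyme that fixes carbon dioxide (AK068266), fell by 3.10 ± 0.86. Photorespiration genes had a median of -1.12 (11 probes, 1 fell, 1 adjusted over the list alone, adjusted p = 0.0459). Histone and DNA replication genes were lower (median -0.38, 5 of 26 fell, 11 adjusted over the list alone, adjusted p = 0.0117), among them histone H4 (AK059019, -2.54 ± 0.69) and a histone H1 (AK073668, -2.05 ± 0.45). Class III peroxidases, which act in the cell wall, had a median of -0.35 (9 of 82 fell and 1 rose, 11 adjusted over the list alone, adjusted p = 0.00174), with AK071392 at -2.49 ± 0.46 and AK105708 at -2.02 ± 0.50. DREB1A, an AP2 factor known for binding the dehydration-responsive element (AK105599), fell by 4.04 ± 0.80, a second AP2 factor (AK073812) fell by 2.46 ± 0.51, and another (AK100575) rose by 2.25 ± 0.36. Also lower were a glucanase that cuts cell wall glucans (AK060867, -3.37 ± 0.67, well above background on 1 of 3 cold arrays) and a trehalose-6-phosphate synthase (AK072066, -2.24 ± 0.47).

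For cold, limma called 2242 of 21289 probes, 1446 higher and 796 lower (64.5% higher, 53.7% with processed signals). With scan day as a block the count was 2104, and of 2152 called probes measured both ways 2147 kept their direction and 1471 their call. The named genes with a shoot array of that day (23 of 25) all kept their direction and differed from the pooled value by at most 0.48. The block's list medians were -0.87 for light harvesting, -1.04 for photorespiration, -0.53 for histones, -0.26 for peroxidases and 0.48 for the proteasome. Separate shoot arrays gave 6255 probes, and scan day as a random block, with shoot arrays also separate, gave 4198. A common 75th percentile gave 1337, and leaving out cold 48 h gave 1385. Calls for AK105609, AK109403, AK059589, AK068266, AK105708 and AK059019 were lost without cold 48 h or cold 72 h (AK068266 also without PEG 24 h or flood 72 h), with log2 values in those fits of 1.08 to 1.26 and of -3.10 to -1.89.

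PEG draws water from the roots, and its comparison with untreated shoot asked what that osmotic stress changed. The group that rose together was the late embryogenesis abundant (LEA) proteins and dehydrins, hydrophilic proteins that accumulate in drying tissues. Of these, 7 of 12 rose and 0 fell, 11 adjusted over the list alone, with a median of 1.94 (adjusted p = 7.08e-09, and adjusted p = 0.751 with an estimated correlation). WSI18, named as induced by water stress (AK064074), rose by 5.27 ± 0.59, 2 dehydrins rose by 4.99 ± 0.98 (AK063517) and 4.22 ± 1.00 (AK071366), and a LEA match (AK107654) rose by 2.55 ± 0.47. A hydrophobic LEA-like protein (AK102039) stood at 2.72 ± 0.94 without passing (adjusted p = 0.112). Oshox6 (AK063685) rose by 5.84 ± 0.70, with time point values of 6.98, 5.92 and 4.62 at 1, 9 and 24 h.

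The abscisic acid-responsive protein (AK063578) rose by 4.60 ± 0.36 in PEG, the protein phosphatases 2C by 4.53 ± 0.51 (AK063334) and 4.20 ± 0.43 (AK069274), and a C2H2 zinc finger protein (AK068861) by 4.14 ± 0.49. A homologue of barley blt101, a small membrane protein gene first known from cold-treated barley (AK070872), rose by 3.78 ± 0.90, and the Clp subunit (AK068727) by 3.55 ± 0.55. Decreases included the proline-rich protein OsPRP2 (AK060275, -3.27 ± 0.57), nitrate reductase, which starts nitrate assimilation (AK102363, -2.64 ± 0.46), and plastid fatty acid desaturases that make trienoic lipids (AK061531, -2.54 ± 0.62, and AK058242, -2.15 ± 0.52). Also lower were a NOD26-like channel (AK072966, -2.27 ± 0.51) and a peroxidase (AK105708, -2.29 ± 0.50).

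Other lists passed in PEG with the preset correlation only, and each lost its call with an estimated one (adjusted p = 0.751). Medians were -0.98 for light harvesting (36 probes, 0 called, 0 adjusted over the list alone, adjusted p = 0.00501) and -1.31 for carbon fixation (14 probes, 0 called, 6 adjusted over the list alone, adjusted p = 0.00788). The median was -0.39 for cytosolic ribosomal proteins (113 probes, 0 called, 0 adjusted over the list alone, adjusted p = 0.00177). Phosphoribulokinase, a carbon fixation enzyme (AK099461), stood at -2.48 ± 0.91 (adjusted p = 0.129). Peroxidases had a median of -0.18 (4 of 82 fell, 10 adjusted over the list alone, adjusted p = 0.0442). Amylases had a median of 0.29 (1 of 19 rose, 1 adjusted over the list alone, adjusted p = 0.0431), which was 0.06 with scan day as a block, where the list no longer passed (adjusted p = 0.443).

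For PEG, limma called 764 of 21289 probes, 434 higher and 330 lower (56.8% higher, 78.2% with processed signals and 70.8% with a common 75th percentile). With scan day as a block the count was 135, and of 744 called probes measured both ways 699 kept their direction and 124 their call. Of the 17 named called genes, 14 had a block value, all 14 in the same direction and 9 called, with gaps up to 0.77. The block's list medians were 1.87 for LEA proteins, -0.97 for light harvesting, -1.21 for carbon fixation, -0.32 for ribosomal proteins and -0.15 for peroxidases. Limma called 0 probes from the 4 arrays of that day alone, with 1972 at an unadjusted p under 0.05. The count was 115 without PEG 9 h, the array with only 66.9% of probes well above background, 160 without PEG 24 h, and 2479 without PEG 1 h. It was 2625 without shoot 2, 1431 without shoot 3 and 414, 341, 420 and 359 without shoots 4, 5, 6 and 7. It was 481 without cold 72 h, 1274 and 1256 without flood and lay-down 6 h and 48 h, and 239, 238 and 310 without flood 24, 48 and 72 h. Calls for AK063685, AK064074, AK063578, AK063334, AK069274, AK068861, AK068727 and AK102363 held in all 19 of these fits. The other 9 named genes lost theirs without PEG 9 h, and some also without PEG 24 h, any cold or flood array, flood and lay-down 24 h or shoots 1 and 4 to 7, at log2 values of 2.29 to 4.58 and of -3.11 to -1.87 in those fits.

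**Figure D2:**
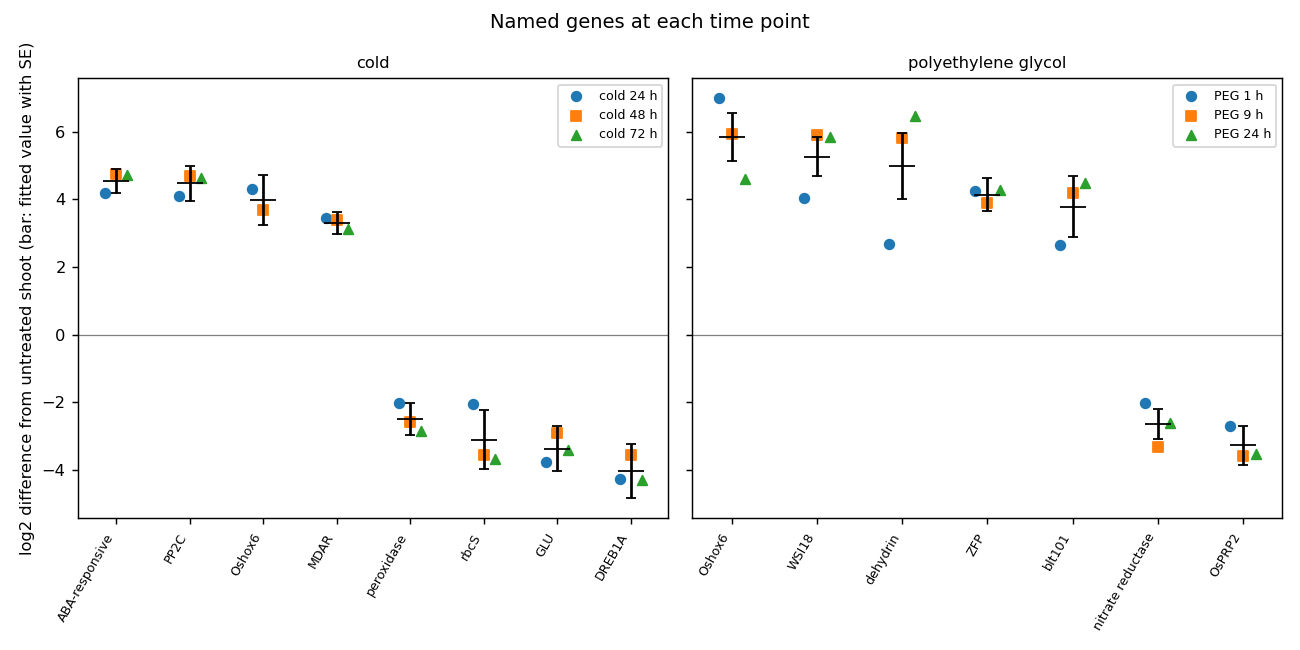
Points give the log2 difference of each cold or PEG time point from untreated shoot for named genes, and black bars the fitted value with its SE. Oshox6 lay at 6.98, 5.92 and 4.62 in PEG at 1, 9 and 24 h, and DREB1A lay between -4.30 and -3.56 in cold.

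Flooding with the plants laid down was compared with untreated shoot for the response to submergence and lodging. Nitrate reductase (AK102363) fell by 3.64 ± 0.46, and uroporphyrinogen III methyltransferase, which makes the sirohaem cofactor of nitrite reductase and was listed under chlorophyll synthesis (AK072497), fell by 2.00 ± 0.33. An aspartate kinase-homoserine dehydrogenase of amino acid synthesis (AK068391) fell by 3.50 ± 0.59, a carotenoid-cleaving enzyme match (AK064824) by 2.78 ± 0.50, a granule-bound starch synthase (AK102058) by 2.62 ± 0.46 and an Mlo7 membrane protein match (AK066134) by 2.55 ± 0.34. Germin-like proteins of the cell wall rose (AK058764, 3.00 ± 0.53, and AK059812, 2.85 ± 0.66), as did cytosolic pyruvate orthophosphate dikinase (AK065739, 2.66 ± 0.46) and phosphoenolpyruvate carboxykinase (AK102392, 2.15 ± 0.45), enzymes around pyruvate. A beta-1,3-glucanase linked to defence (AK068247) rose by 2.48 ± 0.48, the Clp subunit (AK068727) by 2.46 ± 0.55, a match to a salicylic acid methyltransferase (AK068035) by 2.49 ± 0.60, and gibberellin 2-oxidase, which inactivates gibberellins (AK063973), rose 2.64-fold (log2 SE 0.22).

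In the fermentation and sucrose cleavage list, an allyl alcohol dehydrogenase (AK060453), not an ethanol-forming enzyme by its description, fell by 1.77 ± 0.30, and sucrose synthase 3 (AK099406) stood at 2.45 ± 0.73 (adjusted p = 0.0809). Light-harvesting genes had a median of -0.64 (36 probes, 0 called, 3 adjusted over the list alone, adjusted p = 0.00185, and adjusted p = 0.818 with an estimated correlation), and -0.70 against the nearest day's shoot array. A chlorophyll a/b-binding protein (AK058293) stood at -3.18 ± 1.36 (adjusted p = 0.186). A proline-rich protein match (AK059531, 2.31 ± 0.32) and a beta-amylase match (AK070300, 1.74 ± 0.34) were called against the mean of 7 shoot arrays but stood at 0.24 and 0.17 against the nearest day's array. AK070300 reversed to -0.19 against the mean of shoots 2 and 3.

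Limma called 635 of 21289 probes for flooding with lay-down, 422 higher and 213 lower (66.5% higher, 80.5% with processed signals and 28.6% with a common 75th percentile). The nearest day's shoot array gave 22 probes, with 17 of the 17 named called genes in the same direction but 5 called. Shoots 2 and 3 gave 0 by limma, with 1696 at an unadjusted p under 0.05. These treatments had no shoot array on their scan days, so treatment and day cannot be told apart. The count was 12 without flood and lay-down 48 h, 165 without 24 h, and 1823 without 6 h, and 24, 23 and 12 without flood 24, 48 and 72 h, and 416 without cold 72 h. It was 1089 and 267 without PEG 1 h and 24 h, and 408, 2757, 1428, 127, 167, 248 and 83 without shoots 1 to 7 in turn. AK102363, AK066134 and AK059531 were called in all 19 fits. The other 14 named genes lost their calls without flood and lay-down 48 h, and some also without its 24 h array, any flood or cold array, PEG 9 h or 24 h, or shoots 1 and 4 to 7, at log2 values of 1.29 to 3.08 and of -3.50 to -1.77.

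Flooding alone was compared with untreated shoot in the same way. Nitrate reductase (AK102363) fell by 3.77 ± 0.46, the sirohaem enzyme (AK072497) by 2.12 ± 0.33, and the aspartate kinase-homoserine dehydrogenase (AK068391) by 3.40 ± 0.59. The carotenoid-cleaving match (AK064824) fell by 2.88 ± 0.50, the Mlo7 match (AK066134) by 2.15 ± 0.34, peroxidase POX8.1 (AK106109) by 1.95 ± 0.32 and the allyl alcohol dehydrogenase (AK060453) by 1.80 ± 0.30. Root-specific RCc2 (AK062911) rose by 3.68 ± 0.65, cytosolic pyruvate orthophosphate dikinase (AK065739) by 3.40 ± 0.46, a Myb factor (AK066180) by 1.75 ± 0.29, an MtN21 match (AK071286) by 1.71 ± 0.30 and gibberellin 2-oxidase (AK063973) by 1.25 ± 0.22. Sucrose synthase 3 (AK099406) stood at 1.93 ± 0.73 (adjusted p = 0.195) and a beta-amylase match (AK067249) at 2.39 ± 0.82 (adjusted p = 0.163). Light-harvesting genes had a median of -0.63 (36 probes, 0 called, 0 adjusted over the list alone, adjusted p = 0.00104, and adjusted p = 0.933 with an estimated correlation), and -0.61 against the nearest day's array. AK059531 rose by 1.96 ± 0.32 against the mean of 7 shoot arrays but stood at -0.11 against the nearest day's array and against shoots 2 and 3.

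For flooding, limma called 86 of 21289 probes, 31 higher and 55 lower (36.0% higher, 25.0% with processed signals and 21.4% with a common 75th percentile). The nearest day's shoot array gave 26 probes, with 12 of the 13 named called genes in the same direction and 7 called, and shoots 2 and 3 gave 14. The count was 13, 7 and 7 without flood 24, 48 and 72 h, 44, 24 and 48 without cold 24, 48 and 72 h, and 235, 37 and 34 without PEG 1, 9 and 24 h. It was 298, 40 and 227 without flood and lay-down 6, 24 and 48 h, and 28, 1538, 391, 38, 29, 41 and 26 without shoots 1 to 7 in turn. Only AK102363 among the 13 named called genes was called in all 19 fits. The other 12 lost their calls without flood 48 h and 72 h, and some also without flood 24 h, any cold array, PEG 9 h or 24 h, flood and lay-down 24 h or shoots 1, 4, 5 and 7, at log2 values of 1.19 to 3.96 and of -3.53 to -1.70.

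Laying the flooded plants down was tested directly against flooding alone. Nitrate reductase (AK102363), the sirohaem enzyme (AK072497) and pyruvate orthophosphate dikinase (AK065739), named in both comparisons above, were among the 21289 probes tested, and limma called 0 of them at the threshold, with 830 at an unadjusted p under 0.05. With hours of treatment as a block it called 0, with 1461 unadjusted. At this number of samples, simulated 4-fold changes were recovered in 90.9% of cases, 2-fold changes in 50.7% and 1.5-fold changes in 11.9%. The simulation held no scan-day effect, so these shares are not the power of this test. Each flood treatment was scanned on a day of its own, so treatment and day cannot be told apart here.

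Each treatment was also set against the mean of the other 3, a contrast that uses no untreated array. A gene can therefore stand out in 1 treatment because it changed in the others. In cold, enolase of glycolysis (AK069316, 4.02 ± 0.53), the SB100 heat shock match (AK064436, 3.58 ± 0.24) and a phytosulfokine peptide precursor (AK059860, 3.16 ± 0.14) were higher. Lower in cold were isocitrate lyase of the glyoxylate cycle (AK063353, -4.89 ± 0.91), the photosystem II 10 kDa protein (AK062172, -4.39 ± 0.40), the glucanase (AK060867, -4.25 ± 0.39), pathogenesis-related protein 1 (AK060057, -3.37 ± 0.35) and DREB1A (AK105599, -3.06 ± 0.46). Of 52 proteasome genes 32 were higher and 7 lower, 40 adjusted over the list alone (median 0.50, adjusted p = 0.0355, and adjusted p = 0.852 with an estimated correlation). Limma called 12543 of 21289 probes for cold, 6295 higher and 6248 lower (50.2% higher, 37.0% with processed signals), and 3703 with scan day as a random block.

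In PEG against the other treatments, 11 of 12 LEA proteins and dehydrins were higher and 0 lower, 11 adjusted over the list alone (median 1.88, adjusted p = 2.55e-13, and adjusted p = 0.301 with an estimated correlation). These were led by WSI18 (AK064074, 4.65 ± 0.34) and a dehydrin (AK071366, 4.06 ± 0.58). Beside them stood Oshox6 (AK063685, 4.87 ± 0.41), WSI76, named as induced by water stress (AK071812, 3.61 ± 0.37), trehalase, which splits trehalose (AK108163, 3.32 ± 0.11), and a ribosome-inactivating protein (AK103707, 3.28 ± 0.51). A peroxidase (AK058883, -2.41 ± 0.17) and OsPRP2 (AK060275, -2.06 ± 0.33) were lower. Of 113 cytosolic ribosomal protein genes 11 were lower and 1 higher, 12 adjusted over the list alone (median -0.37, adjusted p = 2.01e-05, and adjusted p = 0.783 with an estimated correlation). Limma called 2475 of 21289 probes (50.4% higher, 63.5% with processed signals and 64.3% with a common 75th percentile). The count was 659 without PEG 9 h, 1148 without PEG 24 h and 1583 without flood 48 h, 1350 with separate shoot arrays, 1175 with a common 75th percentile 161 with scan day as a random block and 573 with hours of treatment as a block.

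In flooding with lay-down against the other treatments, the salicylic acid methyltransferase match (AK068035, 3.07 ± 0.34), a germin-like protein (AK059812, 2.94 ± 0.38), pathogenesis-related protein 1 (AK060057, 2.63 ± 0.35) and the DRE-binding proteins 1A (AK105599, 2.35 ± 0.46) and 1B (AK062422, 2.33 ± 0.66) were higher. Oshox6 (AK063685, -3.75 ± 0.41), a protein phosphatase 2C (AK069274, -3.12 ± 0.25) and a beta-amylase match (AK068968, -2.58 ± 0.43) were lower. Of 82 peroxidases 16 were higher than in the other treatments and 1 lower, 17 adjusted over the list alone (median 0.17, adjusted p = 0.00769), with a median against shoot of 0.030. Of 52 proteasome genes 2 were higher and 8 lower, 10 adjusted over the list alone (median -0.24, adjusted p = 0.0113), with a median against shoot of -0.042. Both lists had adjusted p = 0.965 with an estimated correlation. Limma called 3819 of 21289 probes, and 1554 without flood and lay-down 24 h, 1020 without 48 h, 1851 with a common 75th percentile, 1064 with separate shoot arrays and 21 with scan day as a random block. The call for AK062422 was lost without any 1 flood and lay-down array and without flood 24 h or 48 h, at log2 values of 2.16 to 2.45.

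In flooding against the other treatments, RCc2 (AK062911, 3.84 ± 0.38), the photosystem II 10 kDa protein (AK062172, 3.38 ± 0.40), a plasma membrane aquaporin match (AK058613, 2.47 ± 0.37), OsPRP2 (AK060275, 2.38 ± 0.33) and a wall-associated kinase (AK111809, 2.21 ± 0.19) were higher. Lower were Oshox6 (AK063685, -3.53 ± 0.41), a protein phosphatase 2C (AK069274, -3.51 ± 0.25) and a drought-induced ribonuclease (AK061438, -2.36 ± 0.42). Oshox6 and the phosphatase were among the increases against shoot in cold and PEG above. Histone and replication genes were higher than in the other treatments in 7 of 26 cases and lower in 0, 10 adjusted over the list alone (median 0.26, adjusted p = 0.0102, and adjusted p = 0.92 with an estimated correlation). Their median against shoot was -0.061 in flooding, -0.38 in cold, -0.23 in PEG and -0.24 in flooding with lay-down. Peroxidases were higher in 13 of 82 cases and lower in 2 (median against shoot 0.054, and -0.35 in cold), 24 adjusted over the list alone (median 0.17, adjusted p = 0.00365, and adjusted p = 0.709 with an estimated correlation). Limma called 2032 of 21289 probes, and 626, 454 and 727 without flood 24, 48 and 72 h, 1232 with separate shoot arrays and 29 with scan day as a random block.

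**Figure D3:**
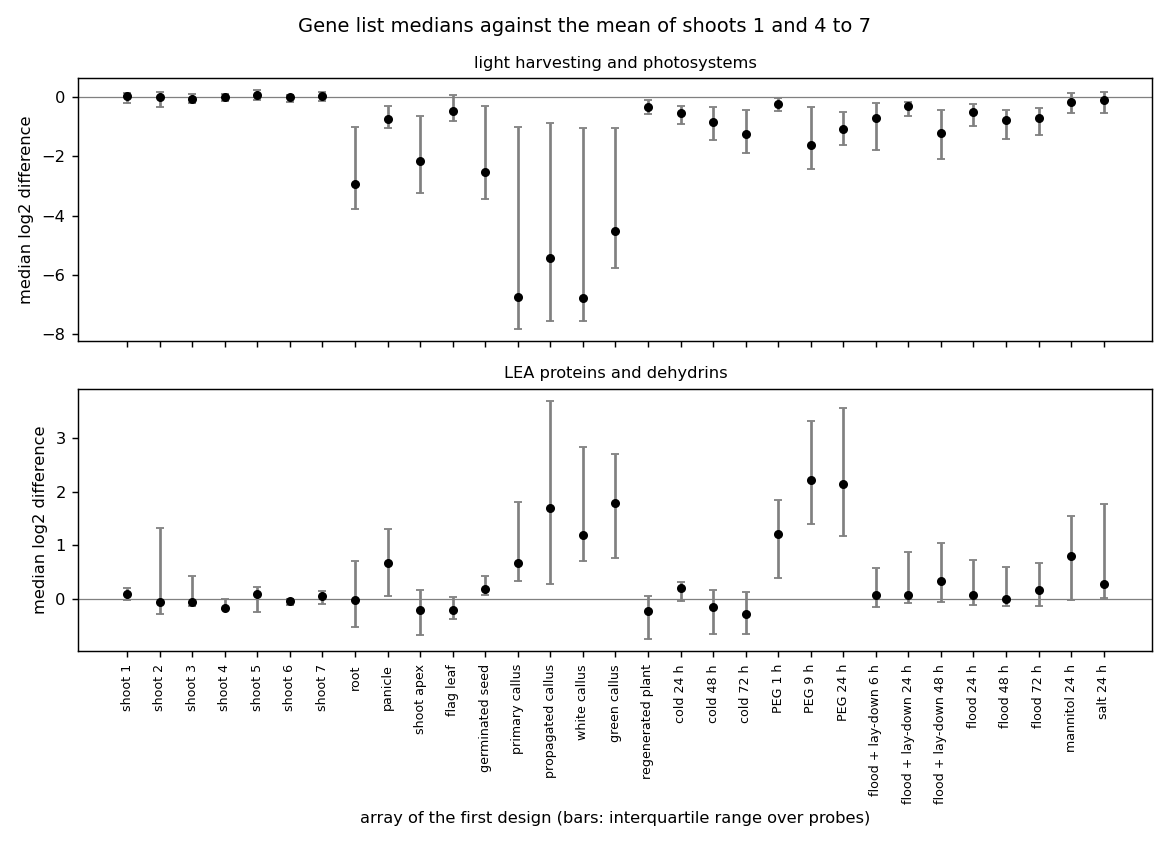
Points give the median log2 difference of the light-harvesting list and of the LEA and dehydrin list on each design 1 array from the mean of shoots 1 and 4 to 7, with bars for the interquartile range over probes. Callus has the lowest light-harvesting medians, and PEG at 9 and 24 h has the highest LEA medians, although the fitted LEA median of 1.94 passed the list test with the preset correlation only.

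Callus, the undifferentiated tissue from which plants are regenerated, was compared with 7 plant organs to ask what sets cultured cells apart. Light-harvesting and photosystem genes were lower: 22 of 35 fell and 0 rose, 24 adjusted over the list alone (median -2.57, adjusted p = 0.0025, and adjusted p = 0.422 with an estimated correlation). They included a type I chlorophyll a/b-binding protein (AK061619, -6.90 ± 0.81), the photosystem II 10 kDa polypeptide (AK105055, -6.39 ± 0.91), Cab26 (AK060904, -6.34 ± 0.94) and a photosystem I subunit (AK058788, -6.19 ± 0.82, n = 4 stages except where given below). Plastocyanin, an electron carrier (AK070447), fell by 5.50 ± 0.78, Rubisco activase (AK058310) by 5.73 ± 1.15 and a Rubisco small subunit (AK058875) by 5.45 ± 1.21. The value for AK058310 is approximate, because its shoot spot, part of the organ reference, was saturated. Aquaporins, which are water channels, were lower too (7 of 27 fell, 0 rose, 7 adjusted over the list alone, median -0.84, adjusted p = 0.0025, and adjusted p = 0.422 with an estimated correlation), with a plasma membrane channel (AK061782, -3.17 ± 0.66) and a NOD26-like channel (AK072966, at least 10.3-fold lower, not well above background in callus, adjusted p = 3.24e-05).

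LEA proteins and dehydrins were higher in callus (6 of 11 rose, 0 fell, 6 adjusted over the list alone, median 1.03, adjusted p = 0.00287, and adjusted p = 0.422 with an estimated correlation), led by an Em protein (AK063677, 6.38 ± 0.56). Others were rab25 (AK063691, 4.40 ± 0.76), a hydrophobic LEA-like protein (AK063592, 4.34 ± 0.61) and WSI18 (AK064074, 5.34 ± 0.62). Pyruvate decarboxylase of ethanol fermentation rose at 2 probes (AK100678, 5.71 ± 0.68, and AK100501, 4.60 ± 0.66), while the fermentation and sucrose cleavage list went both ways (5 of 39 rose, 3 fell, 8 adjusted over the list alone, median -0.01, mean 0.31, adjusted p = 0.656). Alpha-amylases, which break down starch, rose at AK064300 (5.91 ± 0.86) and AK073487 (4.80 ± 0.91), and 6 of 17 amylases rose while 0 fell, 6 adjusted over the list alone (adjusted p = 0.33). GH3 proteins, which conjugate auxin (AK101193, 5.02 ± 0.87, and AK102809, 3.61 ± 0.80), and haemoglobin 1 (AK064054, 6.10 ± 1.13) rose. So did lipid transfer proteins (AK102455, 5.38 ± 1.01, and AK062506, 5.13 ± 0.62), a seed protein precursor match (AK102651, 5.23 ± 0.38) and cinnamyl alcohol dehydrogenase, a lignin enzyme (AK102452, 3.36 ± 0.44).

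Some spots were set aside, so n was 2 for AK064054, AK064300, AK102455, AK062506, AK100501, AK073487 and AK101193, measured on primary and propagated callus alone, which share a scan day. It was 3 for AK100678, AK064074, AK102651, AK058875, AK063691, AK063592, AK102452 and AK102809. Signals were well above background on 1 of 4 callus arrays for AK060904 and 2 of 4 for AK061619, AK058310 and AK058875, and on 3 of 13 reference arrays for AK064300 and 5 of 13 for AK100678 and AK063592. For callus, limma called 3092 of 19733 probes, 2084 higher and 1008 lower (67.4% higher, 77.8% with a common 75th percentile). With scan day as a block the count was 2758, and of 2380 called probes measured both ways all kept their direction and 1933 their call. The block lacks most of the named genes, which were set aside as outlying spots or dim on that day's arrays: only AK063677 (6.35) and AK072966 (-3.61) were measured. The block's list medians were -0.78 for light harvesting, 1.20 for LEA proteins and -0.23 for aquaporins, and the aquaporin list no longer passed (adjusted p = 0.0747). The arrays of the primary and propagated callus day alone gave 609 probes, those of the white and green callus day alone 804, leaving out the white and green callus day 479, and a common 75th percentile 1356. The count was 1667 without primary, 1192 without propagated and 1361 without white callus. Calls were lost for AK101193, AK102809 and AK058875 without primary, for AK064054, AK102455 and AK102809 without propagated, and for AK058875 without white callus, at log2 values of 2.97 to 5.97 and of -5.16 to -4.98.

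**Figure D4:**
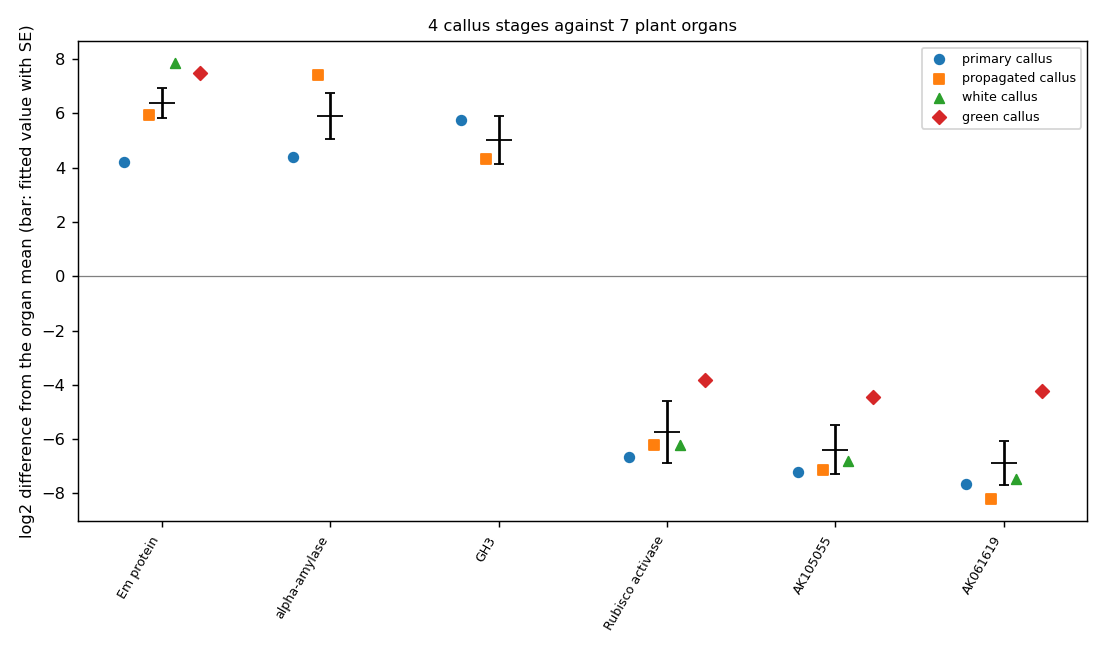
Points give the log2 difference of each callus stage from the mean of 7 plant organs, and black bars the fitted value with its SE. The Em protein lay above the organ mean at all 4 stages, and the photosynthesis genes AK105055 and AK061619 lay below it, with green callus nearest to 0 at -4.43 and -4.25.

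Germinated seed (4 days, whole plant) was compared with shoot on both designs. With an estimated correlation every list named for it lost its call (adjusted p = 0.50). The highest increase was in a lipid transfer protein (AK063493, 7.69 ± 0.21, n = 2 arrays here and below), followed by a thionin, an antimicrobial peptide (AK062831, 6.60 ± 0.20), and a protease inhibitor (AK058739, 6.30 ± 0.20). Pathogenesis-related genes rose in 36 of 88 cases and fell in 10, 48 adjusted over the list alone (median 0.22, adjusted p = 6.32e-05), with a thaumatin-like protein (AK099946, 5.98 ± 0.22), PBZ1 (AK071613, 5.97 ± 0.21) and an endochitinase (AK061042, 4.98 ± 0.21). Glutathione S-transferases, which detoxify by conjugation, rose in 19 of 48 cases and fell in 8, 28 adjusted over the list alone (median 0.24, adjusted p = 8.61e-05), led by AK103699 (5.63 ± 0.21). Glycolysis (12 of 26 rose, 3 fell, 16 adjusted over the list alone, median 0.42, adjusted p = 0.000208) included enolase (AK073611, 2.71 ± 0.21). Alcohol dehydrogenase 2 (AK102799, 3.32 ± 0.22), pyruvate decarboxylase 1 (AK100678, 3.29 ± 0.21), an alpha-amylase (AK064300, 2.35 ± 0.21) rose. So did a glutelin, a seed storage protein (AK107343, 2.74 ± 0.20), and a metallothionein, which binds metals (AK105219, 2.30 ± 0.20). The shoot spot was well above background on 2 of 7 arrays for AK100678, AK064300 and AK107343.

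Cytosolic ribosomal proteins rose in 54 of 104 cases and fell in 7, 69 adjusted over the list alone (median 0.57, adjusted p = 6.32e-05). Proteasome genes rose in 23 of 49 cases with 0 falling, 24 adjusted over the list alone (median 0.46, adjusted p = 6.32e-05). Metallothioneins rose in 6 of 7 with 0 falling, 6 adjusted over the list alone (median 1.06, adjusted p = 6.32e-05). Photosynthesis genes fell: 23 of 32 light-harvesting genes (0 rose, 24 adjusted over the list alone, median -1.75, adjusted p = 2.05e-23) and 11 of 14 carbon fixation genes (2 rose, 13 adjusted over the list alone, median -1.55, adjusted p = 2.57e-11). Glycolate oxidase of photorespiration (AK061719) fell by 5.48 ± 0.21, the photoprotective photosystem II protein PsbS (AK058284) by 5.42 ± 0.21, the 10 kDa protein (AK062172) by 5.23 ± 0.22. Phosphoribulokinase (AK099461) fell by 4.99 ± 0.20, a glyceraldehyde-3-phosphate dehydrogenase subunit (AK071685) by 4.84 ± 0.22 and a chlorophyll a/b-binding protein (AK058293) by 4.44 ± 0.21. Limma called 5019 of 19520 probes, 2697 higher and 2322 lower. With the shoot array of each day the count was 3569, all 19 named genes kept their direction and call with gaps up to 0.19. The list medians there were -1.71 for light harvesting, -1.62 for carbon fixation, 0.56 for ribosomal proteins, 0.44 for the proteasome, 0.28 for pathogenesis-related genes, 0.23 for glutathione S-transferases, 0.33 for glycolysis and 1.20 for metallothioneins. The 1 residual degree of freedom per probe makes the spread borrow almost wholly from other probes.

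Root, panicle, shoot apex and flag leaf were each 1 array, so the differences carry no test and are set beside the same-day shoot array. In root, the iron transporter OsIRT1 (AK107681) was 144-fold higher than shoot, a peroxidase (AK108824) 112-fold, a vacuolar water channel (AK064728) 81.8-fold, root-specific RCc3 (AK109149) 61.3-fold and an ammonium transporter (AK107204) 22.4-fold. Nicotianamine synthase 1, which makes a metal chelator (AK112069), was at least 58.5-fold and a metallothionein (AK105219) at least 42.5-fold higher, bounds because the root spot was saturated, and OsMT-1 (AK103162) was 20.6-fold higher. Lower in root were a lipid transfer protein (AK058921, log2 -7.72), a proline-rich protein (AK062795, -7.04), PsbS (AK058284, -4.42), a chlorophyll a/b-binding protein (AK058293, -4.21) and germin-like protein 5 (AK065284, at least 138-fold lower, a bound because the root signal was not well above background). Light-harvesting genes had a median of -2.83 (36 probes), below all 10000 random lists, and peroxidases 0.46 (80 probes), above all of them. A 2-fold difference was found for 3468 probes, and for 3671 against the same-day shoot array, where the light-harvesting and peroxidase medians were -2.85 and 0.54. The 13 named genes kept their direction there with gaps up to 0.63.

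On the panicle array the anther and pollen list had a median of 0.55 (14 probes). A chitinase (AK071196) was at least 688-fold higher than shoot (saturated in panicle), a pollen allergen match (AK069922) at least 221-fold and beta-expansin EXPB9, which loosens cell walls (AK070187), at least 117-fold (both not well above background in shoot), and an Osc6 homologue (AK064672) 201-fold. MADS-box genes, which specify floral organs, had a median of 1.52 (32 probes), above all random lists, and of 1.02 over all 34 probes, dim ones included, with a MADS box-like protein (AK072683) 76.2-fold, OsMADS45 (AK100263) 49.1-fold and OsMADS8 (AK072867) 37.7-fold higher. Heat shock genes had a median of 0.30 (68 probes, 18 higher by 2-fold), and 0.22 over all 71, with an 18 kDa protein (AK071240) 108-fold, heat shock protein 26 (AK063618) 39.1-fold and HSP101 (AK105433) 18.8-fold higher. The folds for AK064672, AK072683, AK072867 and AK105433 are approximate, because the shoot spot was well above background on 3 of 7 arrays, and on 5 of 7 for AK100263 and AK063618. Nitrate reductase (AK102363, -5.09) was lower, and germin-like protein 5 (AK065284) was at least 137-fold lower. Counts were 2934 probes, and 3118 against the same-day shoot array, where the MADS-box and heat shock medians were 1.5 and 0.37 (0.95 and 0.33 over all probes) and the 12 named genes kept their direction with gaps up to 0.58.

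In the shoot apex, genes of dividing cells were higher: histones and DNA replication had a median of 1.04 (24 probes), the cell cycle 0.69 (41) and cytosolic ribosomal proteins 0.89 (109), each above all random lists. Examples were histone H4 (AK058436, 5.17-fold), ribonucleotide reductase, which makes deoxyribonucleotides (AK068858, 3.64-fold), and a kinesin-like motor (AK063949, 3.45-fold). Homeobox factors included a KNOTTED1-like match of the meristem-associated family (AK107637, 5.98-fold) and an ATH1 match (AK109849, 3.15-fold), and a thionin (AK062831) was 9.76-fold higher. Lower were chloroplast carbonic anhydrase (AK060890, -6.31), catalase (AK066378, -6.04), a chlorophyll a/b-binding protein (AK058293, -4.32) and Rubisco activase (AK058310), at least 67.9-fold lower because the shoot spot was saturated. Counts were 3290 probes, and 3341 against the same-day shoot array, where the medians were 1.02, 0.62 and 0.94 and the 10 named genes kept their direction with gaps up to 0.27.

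The flag leaf array had lower growth genes than seedling shoot. Wall-loosening genes had a median of -0.86 (35 probes), the cell cycle -0.62 (41) and class III peroxidases -0.61 (79), each below all random lists. Over all probes, dim ones included, these medians were -0.53, -0.51 and -0.49. They depended on scaling: the cell cycle stood at -0.98 with a common 75th percentile and -1.43 with processed signals, peroxidases at -0.88 and -1.51, and wall loosening at -0.96 and -1.22. Lower members included xyloglucan endotransglycosylases (AK058291, -5.08, and AK060654, -4.95), and also lower were a beta-tubulin (AK065323, -5.29) and lipid transfer proteins (AK058921, -4.45, and AK060340, at least 267-fold lower, not well above background in flag leaf). Higher were PBZ1 (AK071613, 39.4-fold), a hexose transporter (AK069202, 35.6-fold), a sesquiterpene synthase (AK062280, 29.7-fold), lipoxygenase CM-LOX2 (AK066825, 21.5-fold) and MADS-box genes (AK069331, at least 19.0-fold, not well above background in shoot, and AK111859, 13.0-fold). Counts were 3564 probes (47.3% higher, 37.0% with processed signals and 37.1% with a common 75th percentile), and 3916 against the same-day shoot array, where the medians were -0.79, -0.57 and -0.72 and the 11 named genes kept their direction with gaps up to 0.47.

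The regenerated plant array, on which 58.1% of probes were well above background, had the fewest differences from seedling shoot among these tissues. A protein kinase match (AK069697, 7.07-fold), RIR1a (AK062449, 4.59-fold), pathogenesis-related protein 1 (AK107926, 4.37-fold) and a phosphate transporter (AK101380, 3.96-fold) were higher. A small GTP-binding protein (AK100585) was at least 14.5-fold lower and a TIM13 match (AK059163) at least 10.3-fold lower, both not well above background in the regenerated plant. Counts were 957 probes (26.5% higher, 54.6% with a common 75th percentile) and 802 against the same-day shoot array, where 5 named genes were measured and kept their direction with gaps up to 0.32.

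Mannitol and salt, the osmotic and ionic stresses at 24 h, were each 1 array scanned with shoot 2. In mannitol, LEA proteins and dehydrins had a median of 0.88 (12 probes) and 0.52 against shoot 2, both above all random lists, but over all 13 probes 0.86 and 0.10. A dehydrin (AK063517) was 16.6-fold and WSI18 (AK064074) 11.1-fold higher. The blt101 homologue (AK070872, 9.65-fold), a lectin-like protein (AK062520, 10.7-fold), chitinase IIb (AK060363, 7.56-fold) and PBZ1 (AK071613, 4.89-fold) were higher. A NAC-domain factor (AK071274, -3.09), germin-like protein 5 (AK065284, -2.89) and a xyloglucan endotransglycosylase (AK070734, -2.80) were lower. In salt, the LEA median was 0.47 (0.26 with a common 75th percentile, 0.95 with processed signals) and 0.23 against shoot 2, and over all 13 probes 0.33 and 0.13. The dehydrin (AK063517) was 3.44-fold higher. Chitinase IIb (AK060363, 8.15-fold), the lectin-like protein (AK062520, 8.09-fold) and a Bowman-Birk trypsin inhibitor (AK064050, 3.95-fold) were higher while germin-like protein 5 (AK065284, -3.79) was lower. Counts depended on the shoot array used: 3160 probes for mannitol against the mean of 7 arrays but 399 against shoot 2, and 3013 (57.7% higher, 46.7% with a common 75th percentile) but 350 for salt. Every gene named here for mannitol or salt kept its direction against shoot 2, with gaps up to 0.82.

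On design 2, plants laid down for 24 h had lower cytosolic ribosomal protein genes, with a median of -1.07 (121 probes, 67 lower by 2-fold), below all random lists, and -1.04 against the same-day shoot array. Ribosomal protein S10 (AK073846, -2.72), histone H4 (AK059019, -3.20), the DRE-binding proteins 1B (AK062422, -3.90) and 1A (AK105599, -3.13) and a calcium-binding CCD1 match (AK111852, -3.16) were lower. Higher were an RD22 match, a dehydration-responsive protein (AK105947, 8.40-fold), an Em protein (AK063677, 7.40-fold), ascorbate oxidase (AK105605, 6.28-fold), chitinase IIb (AK060363, 4.42-fold) and a hydrophobic LEA-like protein (AK102039, 3.40-fold). The count was 897 probes, 747 against the same-day shoot array, and 1667 with processed signals, and the 10 named genes kept their direction against that array with gaps up to 0.22.

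After 1 h, 2 peroxidases were higher in both flood treatments, while the list medians were 0.15 with lay-down and 0.095 without (85 probes): Prx5 (AK104277) was 18.1-fold higher with lay-down and 17.2-fold without, and POX8.1 (AK101772) 9.56-fold and 10.8-fold. This POX8.1 probe is not AK106109, the POX8.1 match that fell in flooding against shoot above. Ascorbate oxidase (AK105605) was 6.60-fold and 7.84-fold higher, and the carotenoid-cleaving match (AK064824) was at -2.65 and -2.41. With lay-down, the Clp subunit (AK068727, 7.38-fold) and a WRKY factor (AK065518, 2.82-fold) were higher, and replication protein A1 (AK060582, -2.55), histone H4 (AK059019, -2.64) and the replication clamp PCNA (AK071591, -1.94) were lower. Without it, the submergence-induced protein sip2 (AK103834, 7.14-fold), the ethylene receptor ETR2 (AK111748, 2.93-fold) and sucrose synthase 3 (AK099406, 2.34-fold) were higher, and nitrate reductase (AK102363, -2.47) and DRE-binding protein 1B (AK062422, -2.26) were lower. Medians with and without lay-down were -0.63 and -0.38 for ribosomal proteins and -0.58 and -0.40 for histones and replication, each below all random lists, and against the same-day shoot array the lay-down medians were -0.78 and -0.55. Counts were 1011 probes with lay-down (1175 against the same-day array, 2206 with processed signals, the 9 named genes in the same direction with gaps up to 0.48) and 557 without (1106 with processed signals), which had no shoot array of its day.

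Dye bias is a measure of the technique alone, since both channels held the same RNA. On design 1, limma called 9305 of 20049 probes, 4719 with Cy5 higher and 4586 with Cy3 higher, but the median size was 0.05 and the largest 0.54 on the log2 scale, and the count was 3664 with median centring in place of loess. On design 2, it called 5927 of 20660 probes (3004 and 2923), with a largest size of 0.78. Without the lay-down array it called 0, with 6628 at an unadjusted p under 0.05. Across 19138 shared probes the biases of both designs correlated at 0.525, and 3028 of the 3156 called in both had the same sign.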

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

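Some tests were chosen after the results were seen. They were the tests of a shared scan-day shift and of treated RNA for shoot 2, and the same-day test for white and green callus. So were the scan-day and 1 h tests of 6 genes that include DREB1A, along with the choice of those genes. Of 32 groups tested for an outlying sample 4 had one, where chance gives about 1 in 20.

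Shoot 2 stood apart from the other shoot arrays, with 3288 probes 2-fold away from their mean, and shoot 3 moved with it (r = 0.676 to 0.804 across probes between their differences from shoots 1 and 4 to 7, with no array used as reference for both). Noise in 1 colour channel is argued against, since 86.8% of the 3653 probes that differed in Cy3 differed in the same direction in Cy5, and weak probes are too, since 19.1% of the 5463 brightest probes differed. RNA of treated plants under an untreated label stays open, since the LEA and dehydrin median of -0.056 in shoot 2 does not decide it: 10 of 14 treated arrays also had a median of 0.5 or less. A shift shared by the arrays of that scan day stays open too, since the 97.4% of 3721 probes that moved in the same direction on mannitol and salt restate their correlation with shoot 2. No biological explanation was tested.

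Photosynthesis genes were lower in callus than in the plant organs. Green callus stood apart from the other 3 stages, nearest to the organ mean, at the photosystem II 10 kDa polypeptide (AK105055, -4.43) and Rubisco activase (AK058310, -3.84). The AK058310 value is approximate, because the shoot spot in the organ mean was saturated, but all stages share that mean. Weak arrays were not at issue for primary and propagated callus, with 83.7% and 81.8% of probes well above background. Their light-harvesting median against the shoot array of their day was -5.65. For white and green callus the median was -1.20, and weak arrays and callus cannot be told apart there, because 18 of 36 probes were set aside as uneven or outlying spots on that day's shoot array. Against shoots 1 and 4 to 7 white and green callus had medians of -6.79 (33 probes) and -4.50 (34 probes). Over only the probes measured on that day's shoot array they stood at -1.09 and -1.15 against shoots 1, 4, 5 and 6, so the smaller value reflects which probes were left. Primary and propagated callus lay below root with a median of -2.23, a value that rests on 1 root array of another scan day. It does not decide whether a lack of green tissue is the cause, since a fuller lack than in root would also give a value below root. Plastid development in green callus, which the labels' colours name, stays open as a biological hypothesis and was not tested.

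DREB1A (AK105599), DRE-binding protein 1B (AK062422) and 3 further genes (AK062882, AK106404 and AK071585) were lower than the untreated shoots on 10 to 14 of 14 treated arrays, although stress is known to induce DREB1 genes. The descriptions of AK062882 and AK106404 name only an Arabidopsis gene, so no function is given for them. A calcium-binding CCD1 match (AK111852), the other gene of the 6, was lower on 6 and higher on 8. The group medians were -2.84 in cold, -0.77 in PEG, -1.39 in flooding, -2.20 in mannitol and -0.71 in salt, but -0.00 in flooding with lay-down. A single deviating shoot array is argued against, because 6 of the 7 shoot arrays lay above the median treated array by over 1 (shoot 2 by 0.46). The labels call these 7 arrays technical replicates, so they cannot decide whether the untreated sample itself deviated. For cold, scan day is argued against as the whole cause for these genes (median same-day difference -3.04, 18 of 18 values below 0). That rests on 3 cold arrays against 1 shoot array, over genes chosen after the results were seen. The medians were -1.47 in mannitol, 0.023 in salt, -3.70 in lay-down and -1.54 in flooding with lay-down at 1 h, where DREB1A stood at 0.25. Each of these rests on 1 array against 1 shoot array, shoot 2 for mannitol and salt, over genes chosen after the results were seen. Scan day is therefore left open there. It cannot be told apart for PEG (-0.93), and could not be tested for the floods of design 1, which had no same-day shoot array. Early induction that had passed by 24 h was looked for on the arrays at 1 h. The median was -2.55 in PEG (5 of 6 values below 0). For the 5 genes other than DREB1A in the floods it was -2.21 (10 of 10 below 0). These values show no induction at 1 h. They rest on 1 array per treatment and cannot decide about the hours that were not sampled. Early induction also stays open for DREB1A in the floods (0.26 at 1 h) and for cold, which had no array before 24 h.

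Shoot 7 had 51.5% of its probes well above background, the lowest among the 7 shoot arrays of design 1. Tests of each treatment against the other 3 found differing effects at 12543 probes for cold, 2475 for PEG, 3819 for flooding with lay-down and 2032 for flooding. The salicylic acid methyltransferase match (AK068035) fell in cold and rose in flooding with lay-down, with a tested difference of -4.17 for cold against the other treatments. The Myb factor (AK066180) fell by 1.20 in cold and rose by 1.77 in flooding with lay-down, where it stood at 1.76 against the other treatments.

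Other splits of the same 12 treated samples were used to ask whether chance can be excluded for these counts. For cold, 1 of 100 splits, the real one, called 12543 probes and the highest other called 1408, so chance can be excluded. For PEG, 2 of 100 called as many as 2475 and the highest other called 3079. For flooding with lay-down, 2 of 100 called as many as 3819, and the highest other called 12036. For flooding, 3 of 100 called as many as 2032, and the highest other called 12077. These 3 shares lie under 0.05 but do not exclude chance. The splits also moved the cold arrays between groups, which can widen the spread within groups and lower the counts. The 2 highest splits, which held 0 samples of the real group, called several times the real count and point to a structure of the samples. Each treatment was scanned on a day of its own, cold and PEG with 1 shoot array each, so treatment and scan day cannot be told apart in these contrasts. With scan day as a random block the counts were 3703, 161, 21 and 29. For flooding with lay-down against flooding all 10 splits called as many as the real 0 (highest other 0), and 10 splits are too few for a share under 0.05. For callus, 1 of 100 splits called 3092 probes and the highest other called 1027, so chance can be excluded.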

How the results depend on the processing

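Chosen after the data were seen were leaving out single shoot arrays, scan day as a random block, hours of treatment as a block, shoots 2 and 3 alone, the nearest day's shoot array, the fits within 1 scan day, the callus scan-day alternatives and the same-day shoot arrays for mannitol and salt. Over the named genes, 1244 of 1423 values under the alternatives fixed earlier kept direction and side of the threshold, 57 lost their call, 9 gained one, 113 untested values moved and 0 reversed. Without single arrays, 2354 of 2620 kept both, 258 lost their call and 8 gained one. Under the alternatives added later, 434 of 578 kept both, 102 lost their call, 4 gained one, 35 moved and 3 reversed.

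The reversed values were AK070300 in flooding with lay-down (-0.19 against shoots 2 and 3) and AK059531 in flooding (-0.11 against shoots 2 and 3 and -0.11 against the nearest day's array). The cause was not tested for these or for the counts below, except where fewer arrays or fewer tested probes are part of the alternative.

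Processed signals gave 472 probes for PEG, 210 for flooding with lay-down and 8 for flooding against shoot. They gave 6462 for root, 5738 for panicle, 6814 for shoot apex, 7857 for flag leaf, 2593 for regenerated plant, 7074 for mannitol, 7064 for salt, 1667 for lay-down, 2206 for flooding with lay-down at 1 h and 1106 for flooding at 1 h. A common 75th percentile gave 1337 for cold, 113 for PEG, 21 for flooding with lay-down and 28 for flooding against shoot, 1175 for PEG and 1851 for flooding with lay-down against the other treatments, 1 for flooding with lay-down against flooding, and 1356 for callus. For flooding against shoot, Cy3 alone gave 43, Cy5 alone 46 and no filter on dim probes 42. Without the intensity trend, flooding with lay-down against flooding gave 4. Median centring gave 3664 for dye bias on design 1.

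With the 7 shoot arrays as separate samples, which counts arrays labelled as technical replicates as independent, the counts against shoot were 6255 for cold, 4638 for PEG, 3809 for flooding with lay-down and 2059 for flooding, and against the other treatments 1350 for PEG, 1064 for flooding with lay-down and 1232 for flooding. Scan day as a random block gave 4198, 1956, 30 and 33 against shoot and 3703, 161, 21 and 29 against the other treatments, in the order cold, PEG, flooding with lay-down, flooding. The random block fit also counted the 7 shoot arrays as separate samples. For PEG, scan day as a block gave 135, shoots 2 and 3 gave 139, the nearest day's array 148 and the 4 arrays of that day alone 0 (limma, 1972 at an unadjusted p under 0.05). For flooding with lay-down, shoots 2 and 3 gave 0 (limma, 1696 unadjusted) and the nearest day's array 22, and for flooding 14 and 26. For callus, the day of primary and propagated callus alone gave 609, the day of white and green callus alone 804, and leaving that day out 479. The same-day shoot array gave 399 for mannitol and 350 for salt.

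Leaving out 1 array at a time, counts ran from 1385 to 2773 for cold, 115 to 2625 for PEG, 12 to 2757 for flooding with lay-down and 7 to 1538 for flooding against shoot. Against the other treatments they ran from 10608 to 12830, 659 to 3286, 1020 to 4455 and 454 to 2662 in that order. The range was 0 to 0 for flooding with lay-down against flooding, 1192 to 3850 for callus, 4362 to 4952 for germinated seed, 8840 to 9685 for dye bias on design 1 and 0 (limma, 6628 at an unadjusted p under 0.05) to 6632 on design 2.

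Not run were the value tables in place of levels, since they hold ratios only, leaving out a germinated seed array, which leaves no residual degrees of freedom, and scan day as a fixed block for the flood treatments and for treatments against each other, which share no scan day. For dye bias, arrays other than shoot were left out. No paired analysis was possible because no replicate links a treated sample to an untreated one, but treatments can be matched on hours. With hours of treatment as a block over 9 samples, PEG against the other treatments gave 573, and flooding with lay-down against flooding gave 0 (limma, 1461 at an unadjusted p under 0.05). Signal over background limits the callus and regenerated plant results, since the 4 arrays of their day had 49.9% to 58.1% of probes well above background. It limits the PEG results too, since PEG 9 h had 66.9%.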

Other observations

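Shoot 8, prepared from messenger RNA, differed from the mean of shoots 9 to 11, prepared from total RNA, by 2-fold or more at 1594 probes (1152 higher and 442 lower). Within shoots 9 to 11 the counts were 71, 33 and 206. Across probes, the difference of shoot 2 from shoots 1 and 4 to 7 correlated at -0.00894 to 0.125 with the cold difference, 0.559 to 0.616 with PEG, 0.691 to 0.745 with flooding with lay-down and 0.635 to 0.713 with flooding. These are ranges over 20 ways of dividing the 5 arrays so that none was reference for both differences. Shoot 3 differed from shoots 1 and 4 to 7 at 805 probes.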
